A study of Homo sapiens with 9 samples.

How the data were processed

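RNA from human fibroblasts was measured in 9 libraries: 3 treated with 1% DMSO, 3 with 0.1 µM and 3 with 0.4 µM CDDO-2P-Im, each for 6 h. Per the labels, RNA was extracted with a column kit and libraries were made with a stranded, poly(A)-selecting mRNA protocol. Groups were taken from the labels of each sample.

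A single table was analysed, with 41023 genes by Ensembl identifier, each with coordinates, an estimated count and an FPKM value per library. Its expected counts were made by the authors with cutadapt for trimming, HISAT2 for alignment and StringTie for assembly and quantification, with edgeR also named, per the submitters' processing notes. Versions of those tools are not given in the sources used here. Its FPKM values were deposited by the authors beside the counts, per the file headers, and for genes with 100 counts or more the count divided by FPKM stayed within 1% of a single factor per library for at least 97.6% of genes. The genome build, the annotation and whether counting used the strand are not given in the sources used here. Of the gene identifiers 40864 matched the reference list of names, and 39627 were in GENCODE release 29, where 99.98% overlapped the same GRCh38 locus and 63.2% had the same start and end. Coordinates are printed as the table gives them. The deposited counts were whole numbers, but low values piled up at multiples of 4: in DMSO libraries the number of genes with a count of 4 was 2.47 ± 0.21 times the mean number with 3 or 5 (SD, n = 3). They were therefore read as counts derived from coverage, were used as the whole numbers in the table without further rounding, and a floor of 12 counts over a group (3 steps of 4) was set for genes at 0. That floor covers counting error only.

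The summed count per library was 58529829 to 73291815. The design fixed before the data were examined took the table to hold FPKM alone and named limma on log2(FPKM + 0.5). Because the table also held counts, edgeR's quasi-likelihood test took its place, and limma on FPKM became an alternative. The design had provided for this only where raw counts stood in place of FPKM, so the change was a departure from it. Genes with an FPKM of 1 or more in at least 3 libraries were tested, 11388 in all, and 35 XIST and Y-linked entries were left out. Counts were scaled by TMM and fitted with 1 mean per group over all 9 libraries without a replicate block (edgeR 4.0.16, limma 3.58.1, R 4.3.3), and genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were 0.1 µM with DMSO, 0.4 µM with DMSO and 0.4 with 0.1 µM, with an F-test over the 3 groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

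Gene lists were fixed before the data were examined, 32 in all: NRF2 targets, HSF1 heat shock genes, endoplasmic reticulum chaperones, ATF4 and integrated stress response genes, metallothioneins, proteasome subunits, NF-κB, interferon and STAT3 targets, extracellular matrix, TGF-β response, YAP and TAZ targets, matrix proteases, cholesterol synthesis, mitosis, S phase, p53 targets, immediate early genes, autophagy, apoptosis regulators, hypoxia and glycolysis, aryl hydrocarbon receptor targets, nuclear-encoded respiratory chain, mitochondrially encoded genes, ribosomal proteins, and markers of fibroblasts, keratinocytes, endothelium, immune cells, melanocytes and Schwann cells, smooth muscle and pericytes, and adipocytes. The 27 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation and with limma's fry beside it. Camera compares a list with the other genes, whereas fry asks whether its genes move 1 way on balance: fry called 14, 19 and 17 lists in the 3 comparisons, camera 12, 15 and 14, and camera with an estimated correlation 4, 0 and 0. Some genes stand in more than 1 list, such as 5 of the 21 tested p53 targets.

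Named genes followed a rule fixed before the data were examined. It took, for each comparison, the 8 largest increases and 8 largest decreases among called genes with a mean FPKM of at least 1, no overlap between the groups' libraries and a symbol that is not only a clone, locus, antisense or pseudogene-style identifier. It added up to 4 members of each list by adjusted p at 0.4 µM, up to 2 by adjusted p between doses, and 12 genes that are always named. The rule gave 165 genes, of which the text prints a part, and some are not reported here. Genes outside it are said to be chosen after their values were seen.

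The test was run on simulated counts drawn from the DMSO means for the 11388 genes, with known changes in seeded genes. Of genes changed 2-fold it recovered 82.1% for 0.1 µM against DMSO, 83.6% for 0.4 µM against DMSO and 83.6% between doses. At 1.5-fold it recovered 37.3%, 26.9% and 40.3%, and at 4-fold 98.5% in each. False calls made up 3.97%, 5.44% and 6.33% of calls. In simulated data with 1 list raised 1.5-fold, camera called that list and 0 other lists. Genes were drawn independently there and all other genes were unchanged. That run therefore cannot show how often camera calls lists wrongly where genes move together or many genes change. Libraries of the same group differed by more than sampling noise, so none was a copy of another.

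Alternatives named before the data were examined were pseudocounts of 0.1 and 1 on log2 FPKM, no expression filter, a stricter filter (FPKM of 5), median-of-ratios scaling, quantile normalisation, the replicate number as a block, a fit of only the groups compared, robust and trend-free variance estimates, a 2-fold minimum, an estimated correlation, and leaving out each library. Limma on log2(FPKM + 0.5), the test named in the design, became an alternative once the counts were seen. Added after seeing the data were DESeq2 1.42.0, edgeR's filterByExpr, median-of-ratios factors on the counts, total-count scaling, counts divided by 4, and a fit without mitochondrially encoded genes. Shared controls were simulated 20 times, with the counts of all 9 libraries drawn from the DMSO means and no gene changed.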

Results

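Human fibroblasts, named PDF in the labels, were treated for 6 h with the vehicle (1% DMSO) or with 0.1 or 0.4 µM CDDO-2P-Im, a synthetic oleanane triterpenoid of the class known to activate the transcription factor NRF2. Polyadenylated RNA was sequenced from 3 libraries per group, 9 in all. The summed gene counts per library lay between 58529829 and 73291815, with means of 68329118 ± 4712996 for DMSO, 61085676 ± 3939858 at 0.1 µM and 68199987 ± 1878475 at 0.4 µM (SD, n = 3). On the first principal component of log2 CPM (counts scaled to library size), which held 67.5% of the variance, the DMSO libraries lay between -53.9 and -48.3, the 0.1 µM libraries between -18.0 and -15.9 and the 0.4 µM libraries between 66.6 and 68.2. Pearson's r across genes was 0.973 to 0.984 between libraries of a group and 0.852 to 0.964 between groups, where genes are not independent replicates. The labels number the libraries of a group but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

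Levels are CPM after TMM scaling, as mean ± SD of 3 libraries. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11388 genes. Chromosomes and positions are those of the deposited table.

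The comparison of 0.1 µM with DMSO asked what the lower dose changed. Heat shock genes and most NRF2 targets rose, while the mitochondrially encoded mRNAs fell. HSPA1A (ENSG00000204389; chromosome 6, 31815543 to 31817946), an inducible cytosolic HSP70 chaperone, rose from 202 ± 102 to 5285 ± 410 CPM. HMOX1 (ENSG00000100292; chromosome 22, 35380361 to 35390293), the heme-degrading enzyme heme oxygenase 1, rose from 1086 ± 140 to 8197 ± 679 CPM, a log2 change of 2.92 ± 0.11 (adjusted p = 3.61e-07). In the opposite direction, MT-ND5, a complex I subunit encoded by the mitochondrial genome, fell by 1.93 ± 0.12 on the log2 scale, from 2563 ± 222 to 673 ± 125 CPM.

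All 26 tested HSF1 heat shock genes were higher at 0.1 µM, with a median log2 change of 1.64. Among them were DNAJB1 at 2.36 ± 0.14, DNAJA1 at 1.92 ± 0.07 and BAG3, an HSP70 co-chaperone, at 1.87 ± 0.09. Of 35 NRF2 targets, 30 rose and none fell, with 31 higher when adjusted over the list alone and a median of 1.18. The glutamate-cysteine ligase subunit genes GCLM and GCLC rose by 1.83 ± 0.10 and 1.39 ± 0.10, SRXN1 (sulfiredoxin) by 1.60 ± 0.14, TXNRD1 (thioredoxin reductase) by 0.73 ± 0.09 and NQO1 by 0.80 ± 0.08. Both lists passed the camera set test (adjusted p = 2.70e-70 for heat shock genes and 1.30e-45 for NRF2 targets), and both passed with an estimated correlation (adjusted p = 0.0195 for each). Counts adjusted over the list alone equalled those over all genes tested wherever no second count is given.

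The 13 mitochondrially encoded mRNAs all fell at 0.1 µM, with a median of -1.41, and MT-ND6 fell by 1.78 ± 0.15 and MT-CO3 by 1.19 ± 0.11. This list passed camera (adjusted p = 1.08e-29) and passed with an estimated correlation (adjusted p = 0.0328). The mitochondrially encoded share of all counts was 5.94 ± 0.22% in DMSO and 3.79 ± 0.45% at 0.1 µM. Of 27 nuclear-encoded respiratory chain genes, 1 rose and 1 fell (0 in each direction when adjusted over the list alone) and 25 did not pass. The list had a camera adjusted p of 0.530. The 6 lower genes among 14 TGF-β response and myofibroblast genes included CCN2 (connective tissue growth factor) at -2.01 ± 0.10, TGFBI at -1.04 ± 0.07 and TPM1 (a tropomyosin) at -1.03 ± 0.08. None of those 14 rose, the median was -0.36, and the list passed both with the preset correlation (adjusted p = 2.16e-08) and with an estimated correlation (adjusted p = 0.0195).

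YAP and TAZ targets were mostly lower, with 15 of 19 falling and 2 rising (16 and 2 adjusted over the list alone), and ANKRD1 fell by 1.88 ± 0.11, AMOTL2 by 1.47 ± 0.10 and CCN1 by 1.08 ± 0.09. Their camera adjusted p was 5.31e-11, and the adjusted p = 0.0718 with an estimated correlation. Among 24 NF-κB targets and cytokines, 9 fell and 2 rose (11 and 3 adjusted over the list alone). LIF fell by 2.27 ± 0.12 and IL33 by 1.67 ± 0.09, while TNFAIP6 rose by 1.27 ± 0.09 and IL6 did not pass (-0.53 ± 0.31, adjusted p = 0.235), except without 0.1 µM replicate 2 (-0.92). The NF-κB call (adjusted p = 0.00480) was lost at an adjusted p = 0.424 with an estimated correlation. Extracellular matrix genes had 8 of 25 lower and none higher (9 adjusted over the list alone), among them COL1A1 at -0.46 ± 0.07 and LOXL2 at -0.73 ± 0.07 (adjusted p = 0.00724, and adjusted p = 0.424 with an estimated correlation). Of 13 matrix proteases and inhibitors 5 fell and 2 rose (6 and 2 adjusted over the list alone): PLAT (tissue plasminogen activator) fell by 1.35 ± 0.07, while the collagenase MMP1 rose by 1.37 ± 0.17. That list had an adjusted p = 0.0171, an adjusted p = 0.116 with an estimated correlation, and no call when limma was run on quantile-normalised values.

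ATF4 and integrated stress response genes rose in 13 of 22 cases and fell in 1, with a median of 0.42. DDIT3 (CHOP) was higher by 1.74 ± 0.23 and PPP1R15A (GADD34) by 0.69 ± 0.08. The camera adjusted p was 0.000150, against an adjusted p = 0.215 with an estimated correlation. Proteasome subunits had 10 of 31 higher and none lower (11 adjusted over the list alone), such as PSMC2 at 0.41 ± 0.08, and p53 targets had 6 of 21 higher and 1 lower (6 and 2), such as CDKN1A at 1.42 ± 0.09 and MDM2 at 0.96 ± 0.08. Both lists passed camera (adjusted p = 0.00191 and 0.00438) and lost the call with an estimated correlation (adjusted p = 0.753 and 0.116). None of 38 ribosomal protein genes passed singly, although the list did (median 0.25, adjusted p = 0.00797, and adjusted p = 0.830 with an estimated correlation). The ribosomal call ended without DMSO replicate 1 (median 0.15) or without 0.1 µM replicate 2 (median 0.13).

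The other lists did not pass camera at 0.1 µM. Endoplasmic reticulum chaperones had 3 of 20 higher (1 adjusted over the list alone), with HSPA5 (BiP) at 0.14 ± 0.06 (adjusted p = 0.136). Interferon-stimulated genes had 5 of 22 higher, cholesterol genes 5 of 23 higher and 2 lower, S phase genes 3 of 19 higher and 2 lower, and hypoxia and glycolysis genes 4 of 18 higher and 4 lower. Immediate early genes were split between 6 higher and 7 lower of 27 (7 and 7 adjusted over the list alone), autophagy genes between 5 and 4 of 22 (7 and 6) and apoptosis regulators between 3 and 2 of 15 (4 and 3). STAT3 targets had 2 of 14 higher and 3 lower, metallothionein and zinc response genes 2 of 6 higher (2 higher and 1 lower adjusted over the list alone), including SLC30A1, a zinc exporter, at 1.64 ± 0.10, and none of 10 mitosis genes passed. The camera adjusted p of these lists ran from 0.0987 for metallothioneins upward; interferon-stimulated genes (adjusted p = 0.123, median 0.21) passed with limma on FPKM, and metallothioneins passed without DMSO replicate 2 (median 0.07) or without 0.1 µM replicate 3 (median 0.06). Medians and the direction of camera differed in sign for metallothioneins (median -0.14), STAT3 targets (-0.04) and smooth muscle markers (-0.06, and 0.16 with the filterByExpr filter), and S phase genes had a median of 0.11 beside a mean of -0.01.

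The 8 largest named increases at 0.1 µM were HSPA1A at 4.71 ± 0.36, HSPA1B at 4.56 ± 0.31, DDIT4L at 3.86 ± 0.24, DNAJA4 at 3.81 ± 0.19, HSPA6 at 3.40 ± 0.77, HES5 at 3.23 ± 0.37, TNFSF9 at 3.20 ± 0.25 and OSGIN1 at 3.15 ± 0.22. HSPA6 was at 4.05 without DMSO replicate 3, and HES5 at 3.89 without DMSO replicate 2. Reads of HSPA1A and HSPA1B, and of HSPA6 and HSPA7, come from near-identical copies, so the division between the copies is uncertain. The 8 largest decreases were the mitochondrial tRNA genes MT-TT (-3.26 ± 0.22), MT-TL2 (-2.69 ± 0.29), MT-TE (-2.64 ± 0.24), MT-TD (-2.64 ± 0.35) and MT-TS2 (-2.54 ± 0.31) and the keratin-related genes KRT18 (-3.22 ± 0.72), KRTAP1-5 (-2.92 ± 0.42) and KRT34 (-2.54 ± 0.21). KRT18 varied among the DMSO libraries from 3.90 to 34.5 CPM and its change was -2.04 without DMSO replicate 1.

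In total 1388 genes were higher and 1629 lower at 0.1 µM, 26.5% of those tested, and 366 and 238 of them changed at least 2-fold. The groups' libraries did not overlap for 44.4% of genes, where chance gives 10%. Without DMSO replicate 3 the number of lower genes was 1067, and without 0.1 µM replicate 2 it was 1083.

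**Figure D1:**
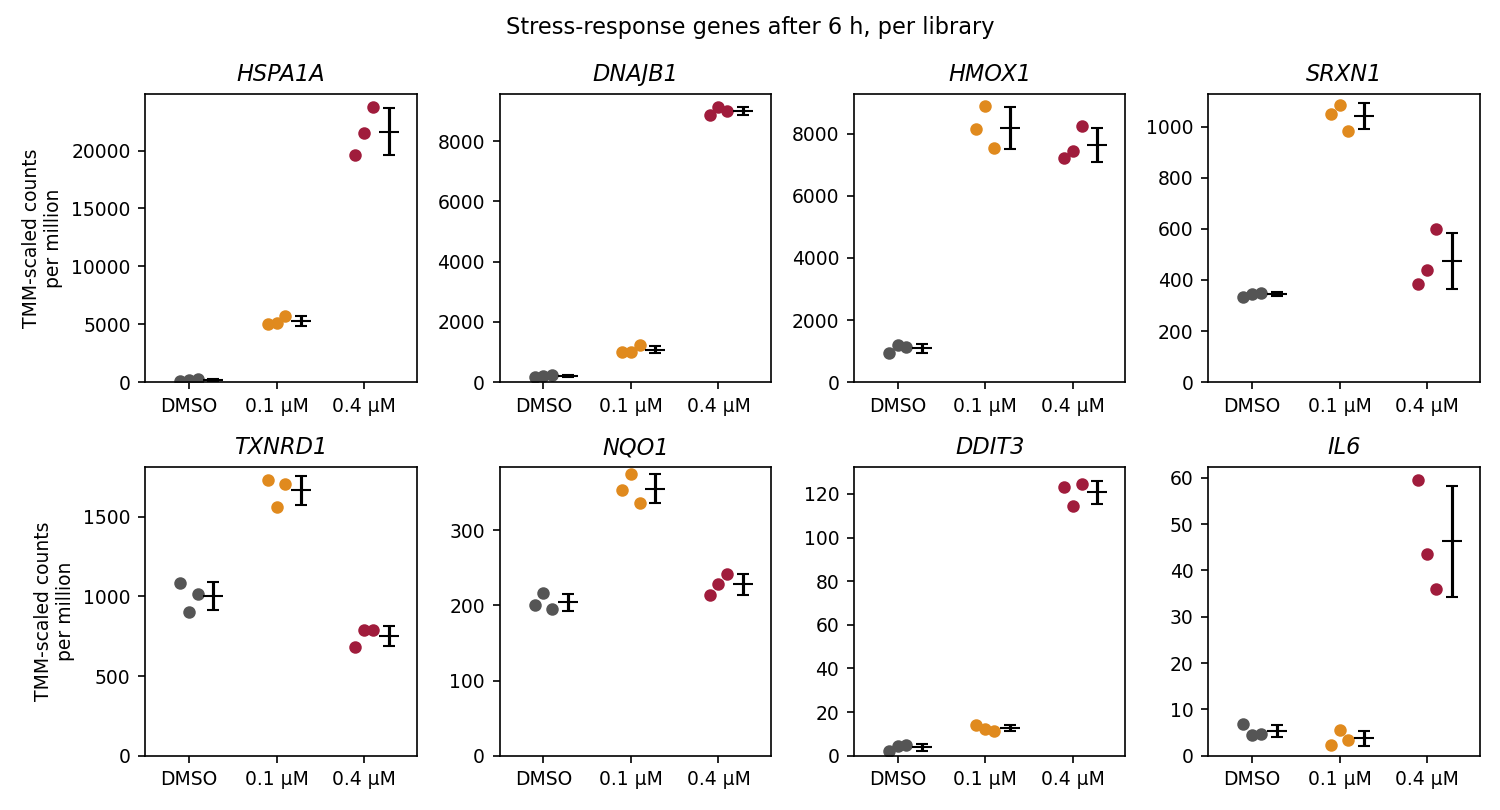
Levels of named genes in CPM (linear axis from 0) for DMSO, 0.1 µM and 0.4 µM, with each point a library and each bar the mean ± SD of 3 libraries. HSPA1A rose from 202 to 5285 and 21637 CPM, whereas SRXN1, TXNRD1 and NQO1 lay lower at 0.4 µM than at 0.1 µM.

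The comparison of 0.4 µM with DMSO asked what the higher dose changed. Heat shock genes rose further than at 0.1 µM, the stress transcription factor genes ATF3 and DDIT3 were higher than in DMSO, and the mitochondrially encoded mRNAs were lower. HSPA1A reached 21637 ± 2048 CPM, DNAJB1 rose from 211 ± 39.2 to 8997 ± 130 CPM (5.41 ± 0.16, adjusted p = 2.33e-09) and BAG3 rose by 4.47 ± 0.10. DDIT3 rose from 3.78 ± 1.41 to 121 ± 5.36 CPM (5.00 ± 0.25), and NR4A1, an orphan nuclear receptor, by 5.44 ± 0.14. MT-CO3 (mitochondrial genome, 9207 to 9990) fell by 2.95 ± 0.12, from 4217 ± 386 to 546 ± 57.9 CPM, and the cytoplasmic actin gene ACTB fell by 1.07 ± 0.09 (adjusted p = 2.03e-06).

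How the libraries were scaled mattered at this dose. With TMM scaling the median change of all tested genes was 0.03, and of the called genes 50.8% were higher, 3753 against 3637 lower. With total-count scaling the median was -0.26 and 30.3% of the called genes were higher, 2255 against 5196 lower. The 10 most abundant genes held 9.80 ± 0.16% of counts in DMSO and 13.7 ± 0.18% at 0.4 µM. Changes are relative to the TMM median.

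All 26 heat shock genes rose at 0.4 µM, with a median of 3.36, including HSPH1 at 4.06 ± 0.10, UBB (polyubiquitin) at 4.32 ± 0.11 and DNAJA1 at 3.39 ± 0.08. The camera adjusted p was 8.27e-60, and the adjusted p = 0.0509 with an estimated correlation. No list kept its call at 0.4 µM with an estimated correlation, and heat shock genes had the lowest value. NRF2 targets rose in 22 of 35 cases and fell in 4, with a median of 0.62 (adjusted p = 0.000204, and adjusted p = 0.336 with an estimated correlation). SQSTM1 (the autophagy receptor p62) rose by 3.13 ± 0.12, HMOX1 by 2.82 ± 0.11 and GCLC by 1.83 ± 0.10, while TXNRD1 fell by 0.41 ± 0.09 and GSR (glutathione reductase) by 0.44 ± 0.08. NQO1 did not pass (0.16 ± 0.08, adjusted p = 0.0935) but did with the stricter expression filter (0.20), and the call of SRXN1 (0.47 ± 0.14) ended with total-count scaling (0.17) and with quantile normalisation (0.04).

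ATF4 and integrated stress response genes rose in 18 of 22 cases and fell in 1, with a median of 1.51. PPP1R15A rose by 4.11 ± 0.08, DDIT4 by 4.16 ± 0.12, ATF3 by 4.13 ± 0.17 and SESN2 by 2.98 ± 0.09 (camera adjusted p = 1.47e-16, and adjusted p = 0.0514 with an estimated correlation). Of 27 immediate early genes 16 rose and 7 fell, with a median of 1.31. IER5 rose by 5.37 ± 0.12 and BTG2 by 4.73 ± 0.12, whereas DUSP6, an ERK phosphatase, fell by 3.28 ± 0.14. Their adjusted p was 4.64e-08, or adjusted p = 0.191 with an estimated correlation. STAT3 targets had 10 of 14 higher and 1 lower, among them PIM3 at 2.48 ± 0.10 and SOCS3 at 2.12 ± 0.09 (adjusted p = 2.64e-05, and adjusted p = 0.139 with an estimated correlation). Interferon-stimulated genes had 14 of 22 higher and none lower, with OASL at 2.92 ± 0.19 and IRF1 at 2.39 ± 0.13 (adjusted p = 0.0103, and adjusted p = 0.139 with an estimated correlation). That interferon call ended with the stricter expression filter.

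Cholesterol synthesis and uptake genes rose in 18 of 23 cases and fell in 3 (19 and 3 adjusted over the list alone), with a median of 0.52. INSIG1, which retains SREBP precursors in the endoplasmic reticulum, rose by 3.11 ± 0.08 and IDI1 by 1.24 ± 0.07 (list adjusted p = 7.19e-05, and adjusted p = 0.139 with an estimated correlation). Autophagy genes had 12 of 22 higher and 2 lower, such as MAP1LC3B (LC3B) at 1.00 ± 0.06 and GABARAPL1 at 1.11 ± 0.08, and p53 targets had 12 of 21 higher and 5 lower, such as CDKN1A at 2.24 ± 0.10, beside MDM2 at -0.03 ± 0.08, which was called lower with total-count scaling (-0.33). Both passed camera (adjusted p = 0.0126 and 0.0130) and lost the call with an estimated correlation (adjusted p = 0.139 for each), autophagy also with total-count scaling and p53 targets with quantile normalisation or without an expression filter. Hypoxia and glycolysis genes had 8 of 18 higher and 4 lower, among them ADM (adrenomedullin) at 3.02 ± 0.09 and PFKFB3 at 2.31 ± 0.09. Their median was 0.27 but -0.02 with total-count scaling, and the list had an adjusted p = 0.0103, an adjusted p = 0.137 with an estimated correlation, and no call with limma on FPKM. Endoplasmic reticulum chaperones had 10 of 20 higher and 3 lower, with HERPUD1 at 2.66 ± 0.08, HSPA5 at 1.45 ± 0.06 and DNAJB9 at 1.38 ± 0.07, and their median of 0.23 became -0.06 with total-count scaling. Their call (adjusted p = 0.0202) ended with that scaling and at an adjusted p = 0.234 with an estimated correlation.

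The 13 mitochondrially encoded mRNAs again all fell, with a median of -2.02 and MT-ND6 at -3.62 ± 0.17, MT-ND5 at -2.72 ± 0.13 and MT-ND1 at -2.57 ± 0.14 (adjusted p = 4.31e-17, and adjusted p = 0.137 with an estimated correlation). Mitochondrially encoded genes made up 1.48 ± 0.18% of counts at 0.4 µM. Of the 27 nuclear-encoded respiratory chain genes 3 rose and 5 fell, NDUFS1 by 0.58 ± 0.07, and the list had a camera adjusted p of 0.994, a median of 0.07 that became -0.22 with total-count scaling, and a camera direction opposite to its median. TGF-β response and myofibroblast genes had 8 of 14 lower and 3 higher, with CCN2 at -2.50 ± 0.10 and SMAD7, an inhibitor of the pathway, at 0.65 ± 0.07. YAP and TAZ targets had 7 of 19 lower and 2 higher, with F3 (tissue factor) at -2.31 ± 0.07 and AMOTL2 at -1.63 ± 0.10. These lists passed camera (adjusted p = 0.0126 and 0.00493), and both calls were lost with an estimated correlation (adjusted p = 0.149 and 0.294) and with limma on FPKM, quantile-normalised or not.

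Ribosomal protein genes rose in 32 of 38 cases (33 adjusted over the list alone) with a median of 0.35, which became -0.03 with quantile normalisation. RPS19 was at 0.65 ± 0.17 and RPL3 at 0.50 ± 0.10, each without a call with total-count scaling (0.36 and 0.21), and RPL4 turned from 0.23 ± 0.07 to -0.06 with total-count scaling and had no call without DMSO replicate 3 (0.22). The list passed camera (adjusted p = 0.0361, and adjusted p = 0.993 with an estimated correlation) but not with total-count scaling, without DMSO replicate 1 (median 0.28) or without 0.4 µM replicate 3 (median 0.29).

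The remaining lists did not pass camera at 0.4 µM. NF-κB targets and cytokines went both ways, 11 higher and 8 lower of 24 (11 and 11 adjusted over the list alone), with IL6 rising by 3.11 ± 0.32 from 5.35 ± 1.25 CPM in DMSO, TNFAIP2 rising by 2.76 ± 0.10 and IL33 falling by 2.28 ± 0.10. Their median was 0.21, and -0.08 with total-count scaling. Extracellular matrix genes were 10 higher and 8 lower of 25 (11 and 9), with FBLN1 at 0.63 ± 0.07 and COL1A1 at -0.58 ± 0.07, and their median of 0.14 was opposite in sign to the mean of -0.03 and to the median with quantile normalisation (-0.19), total-count scaling (-0.15) or limma on FPKM (-0.15). Matrix proteases and inhibitors had 8 of 13 higher and 3 lower (8 and 4), with MMP10 at 4.30 ± 0.46 and TIMP3 at -1.70 ± 0.07. Proteasome subunits had 6 of 31 higher and 1 lower (4 and 1), with PSMB1 at 0.61 ± 0.12 and PSMD11 at -0.55 ± 0.09, apoptosis regulators 8 of 15 higher and 3 lower, with BCL2L11 (BIM) at 3.31 ± 0.19 and BAK1 at -1.89 ± 0.12, and mitosis genes 1 of 10 in each direction, AURKA at 2.80 ± 0.16 and CCNB1 at -0.95 ± 0.14. The medians of these 3 lists (0.08, 0.26 and 0.08) became negative with total-count scaling, and those of proteasome and mitosis genes also with the filterByExpr filter (-0.06 and -0.36) and quantile normalisation (-0.03 and -0.04). S phase genes had 4 of 19 higher and 7 lower (4 and 6), with MCM3 at -1.24 ± 0.13 and SLBP at 1.24 ± 0.07, and metallothionein and zinc response genes 2 of 6 higher, SLC30A1 at 0.70 ± 0.10 and MT1X at 1.22 ± 0.18. The camera adjusted p values of all these lists were 0.757 or higher.

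Among the 8 largest named increases at 0.4 µM were HSPA7 at 8.66 ± 0.77, HSPA6 at 8.36 ± 0.96, DNAJA4 at 6.79 ± 0.22, HSPA1A at 6.74 ± 0.40, HSPA1B at 6.58 ± 0.34, HES5 at 6.33 ± 0.39 and CALCA at 6.25 ± 1.00. Single DMSO libraries moved some of these: HSPA7 and HSPA6 were at 9.25 and 9.01 without replicate 3, HES5 at 7.001 without replicate 2, and CALCA at 5.64 without replicate 1 and 6.90 without replicate 2. HES5 and CALCA were near 0 in DMSO, with 8, 22 and 8 counts and 0, 15 and 11 counts. Among the 8 largest decreases were the mitochondrial tRNA genes MT-TE (-5.82 ± 0.30), MT-TL2 (-5.26 ± 0.36), MT-TS2 (-5.09 ± 0.38), MT-TN (-4.96 ± 0.22), MT-TA (-4.94 ± 0.22) and MT-TT (-4.94 ± 0.25). At 0.4 µM MT-TL2 had 5, 7 and 2 counts and MT-TS2 had 8, 5 and 3. Both were near the floor, so the size of their falls is uncertain. PPAN-P2RY11, a readthrough locus whose reads overlap its 2 component genes, was at 9.11 ± 4.41 CPM in DMSO and at 0 in all 0.4 µM libraries, at least 134-fold lower at a floor of 12 counts over the group. The last of the 8, UPK3BL1, varied among DMSO libraries from 0.351 to 5.78 CPM, and its call (-5.80 ± 1.82, adjusted p = 0.0166) ended with limma on log2(FPKM + 0.5), with a robust variance estimate, and without DMSO replicate 1 (-4.46), 0.4 µM replicate 1 (-5.25) or 0.4 µM replicate 3 (-5.24). UPK3BL1 had 0, 8 and 0 counts at 0.4 µM, under the floor of 12 over the group, so the size of its fall was not measured. Without 0.4 µM replicate 2, where the libraries left had 0 counts, the fitted value was -10.4.

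At 0.4 µM 64.9% of tested genes were called, 1360 higher and 1223 lower by at least 2-fold, and the groups' libraries did not overlap for 68.4% of genes, where chance gives 10%. Over the 3 groups together 7900 genes differed by the quasi-likelihood F-test.

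**Figure D2:**
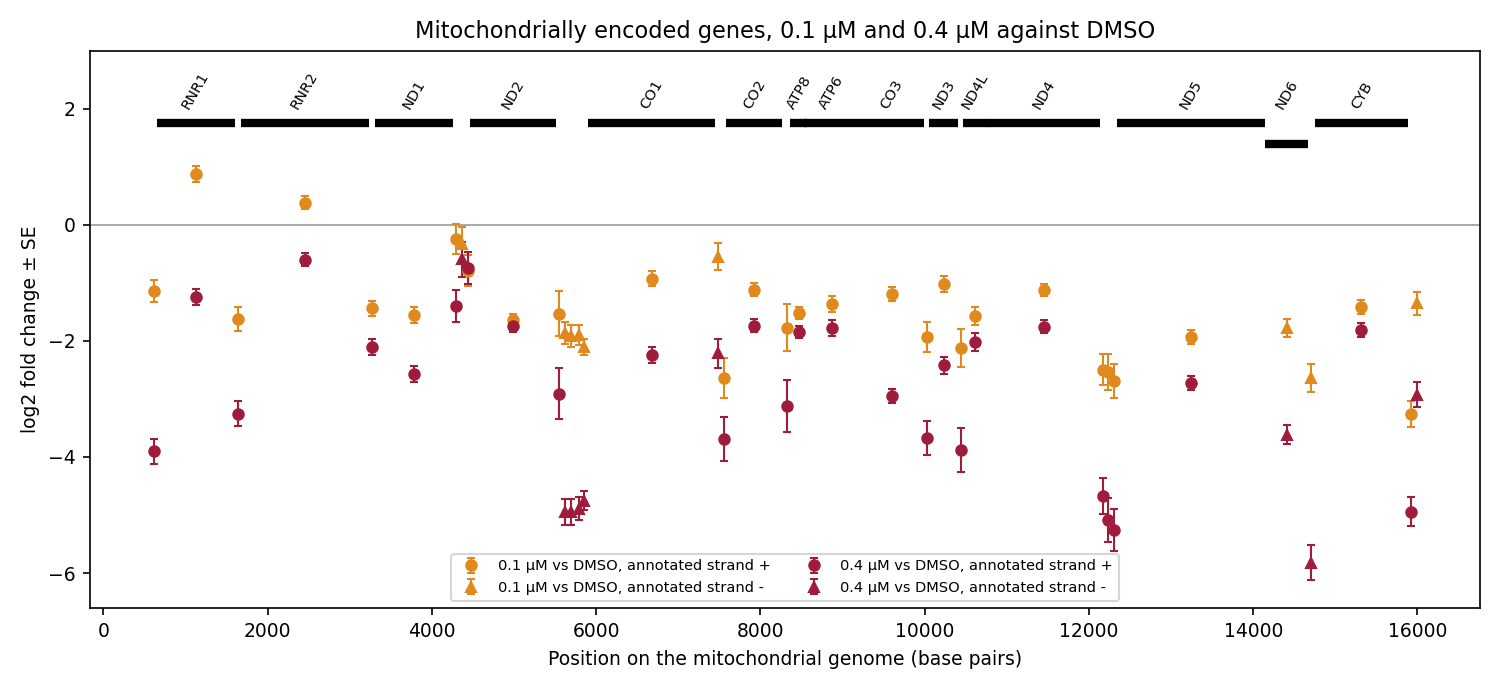
Log2 fold change ± SE of each mitochondrially encoded gene against DMSO by its position on the mitochondrial genome (base pairs), for 0.1 and 0.4 µM, with circles and triangles for the annotated strands. The 2 rRNA genes at the left lay above 0 at 0.1 µM (0.88 and 0.38) and below 0 at 0.4 µM (-1.25 and -0.60), while all 13 mRNAs lay below 0 at both doses.

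The comparison of 0.4 with 0.1 µM asked how the doses differed. Heat shock genes were higher at 0.4 µM than at 0.1 µM, whereas some NRF2 targets, such as GCLM, TXNRD1 and SRXN1, were lower. DNAJB1 was higher by 3.05 ± 0.14, DDIT3 by 3.26 ± 0.23 and IL6 by 3.64 ± 0.33 (adjusted p = 8.31e-06). GCLM was lower by a log2 difference of -1.26 ± 0.09, with 254 ± 11.2 CPM at 0.1 µM and 106 ± 12.9 at 0.4 µM (adjusted p = 2.53e-06). TXNRD1 lay at -1.14 ± 0.09, SRXN1 at -1.13 ± 0.14 and NQO1 at -0.64 ± 0.08, all lower. HMOX1 did not pass (-0.10 ± 0.10, adjusted p = 0.436) except where total-count scaling (-0.39), quantile normalisation or FPKM without further scaling was used.

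Of the 35 NRF2 targets 20 were lower and 6 higher at 0.4 µM than at 0.1 µM, with a median of -0.43 (adjusted p = 0.000338, and adjusted p = 0.348 with an estimated correlation). SQSTM1 was higher by 0.84 ± 0.12 and GSR lower at -1.05 ± 0.08. All 26 heat shock genes were higher, with a median of 1.78 (adjusted p = 1.23e-31, and adjusted p = 0.0959 with an estimated correlation). ATF4 and integrated stress response genes had 17 of 22 higher and none lower (19 adjusted over the list alone), with DDIT4 at 3.70 ± 0.12 and PPP1R15A at 3.43 ± 0.08, and the lowest value with an estimated correlation of this comparison (adjusted p = 7.48e-18, and adjusted p = 0.0908 with an estimated correlation). No list passed here with an estimated correlation. Mitochondrially encoded mRNAs had 12 of 13 lower, with a median of -0.63 (adjusted p = 5.19e-05, and adjusted p = 0.348 with an estimated correlation).

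Immediate early genes had 19 of 27 higher and 4 lower, with IER5 at 4.12 ± 0.11 and BTG2 at 4.03 ± 0.12, STAT3 targets 10 of 14 higher and none lower (11 adjusted over the list alone), with SOCS3 at 2.91 ± 0.09 and JUNB at 1.90 ± 0.09, and cholesterol genes 18 of 23 higher and 2 lower, with INSIG1 at 2.23 ± 0.07. These lists passed camera (adjusted p = 1.88e-13, 5.59e-08 and 4.72e-06) and lost the call with an estimated correlation (adjusted p = 0.148, 0.139 and 0.139). Hypoxia and glycolysis genes had 7 of 18 higher and 1 lower (median 0.15, and -0.14 with total-count scaling), with ADM at 2.86 ± 0.09, NF-κB targets 12 of 24 higher and 5 lower (12 and 6), with TNFAIP2 at 2.11 ± 0.10, and interferon-stimulated genes 12 of 22 higher and 1 lower, with IRF1 at 1.55 ± 0.12. Their camera adjusted p values were 0.00247, 0.0161 and 0.0236, and with an estimated correlation adjusted p = 0.0959, 0.391 and 0.225. The NF-κB and interferon calls ended without 0.4 µM replicate 1 (medians 0.37 and 0.44) and with the stricter expression filter, and the hypoxia call ended with limma on FPKM.

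Autophagy genes had 13 of 22 higher, with OPTN (optineurin) at 0.81 ± 0.06, endoplasmic reticulum chaperones 9 of 20 higher and 2 lower (median 0.23, and -0.06 with total-count scaling), with HERPUD1 at 2.38 ± 0.08, and matrix proteases 8 of 13 higher and 1 lower, with PLAU (urokinase) at 1.82 ± 0.14. These passed camera (adjusted p = 0.0211, 0.0193 and 0.0391), none passed with total-count scaling, and all were lost with an estimated correlation (adjusted p = 0.206, 0.262 and 0.183). The protease call also ended without DMSO replicate 1 (median 0.36). Proteasome subunits had 7 of 31 lower and none higher (6 adjusted over the list alone), with PSMD11 at -0.82 ± 0.09, without passing (adjusted p = 0.182), although that list passed with quantile normalisation (median -0.23) and without 0.4 µM replicate 3 (median -0.23).

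Lists that did not pass in this comparison, with camera adjusted p values of 0.135 or higher, also included extracellular matrix genes with 12 of 25 higher and 3 lower, YAP and TAZ targets with 10 of 19 higher and 6 lower, of which ANKRD1 was higher by 1.03 ± 0.11, and p53 targets with 10 of 21 higher and 5 lower, of which MDM2 lay at -0.99 ± 0.08. The p53 median of 0.19 became -0.10 with total-count scaling. TGF-β response genes had 4 of 14 in each direction (5 in each adjusted over the list alone; median 0.09, and -0.20 with total-count scaling), apoptosis regulators 5 of 15 higher and 2 lower (4 and 2; median 0.19, and -0.10 with total-count scaling), S phase genes 3 of 19 higher and 6 lower, and mitosis genes 1 of 10 in each direction (median 0.32, and -0.02 with the filterByExpr filter). Ribosomal protein genes had 3 of 38 higher (0 adjusted over the list alone; median 0.14, and -0.15 with total-count scaling), nuclear-encoded respiratory chain genes 1 of 27 higher and 3 lower (0 and 2), and metallothionein genes 1 of 6 lower, with a median of 0.14 opposite to the camera direction and to the median with total-count scaling (-0.14).

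Largest among the named increases from 0.1 to 0.4 µM were HSPA7 at 5.74 ± 0.67, HSPA6 at 4.96 ± 0.82, RRAD at 4.58 ± 0.15, ZNF331 at 4.57 ± 0.25, DUSP2 at 4.57 ± 0.25, NR4A3 at 4.57 ± 0.24, CALCA at 4.54 ± 0.88 and NR4A2 at 4.42 ± 0.25. CALCA had 30, 48 and 0 counts at 0.1 µM and was at 5.38 without 0.1 µM replicate 2. Among the largest decreases were PPAN-P2RY11 (at least 94.4-fold), MT-TE at -3.18 ± 0.28, EPGN, an epidermal growth factor family ligand, at -3.13 ± 0.17, MT-TA at -3.08 ± 0.21, DUSP6 at -3.07 ± 0.14, MT-TN at -3.04 ± 0.21 and MT-TC at -2.99 ± 0.18. Between the doses 3334 genes were higher and 3157 lower at 0.4 µM, 57.0% of those tested, of which 51.4% were higher. With total-count scaling 26.3% were higher, 1799 against 5048, at a median shift of -0.27 over all genes. The libraries did not overlap for 62.1% of genes, where chance gives 10%.

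**Figure D3:**
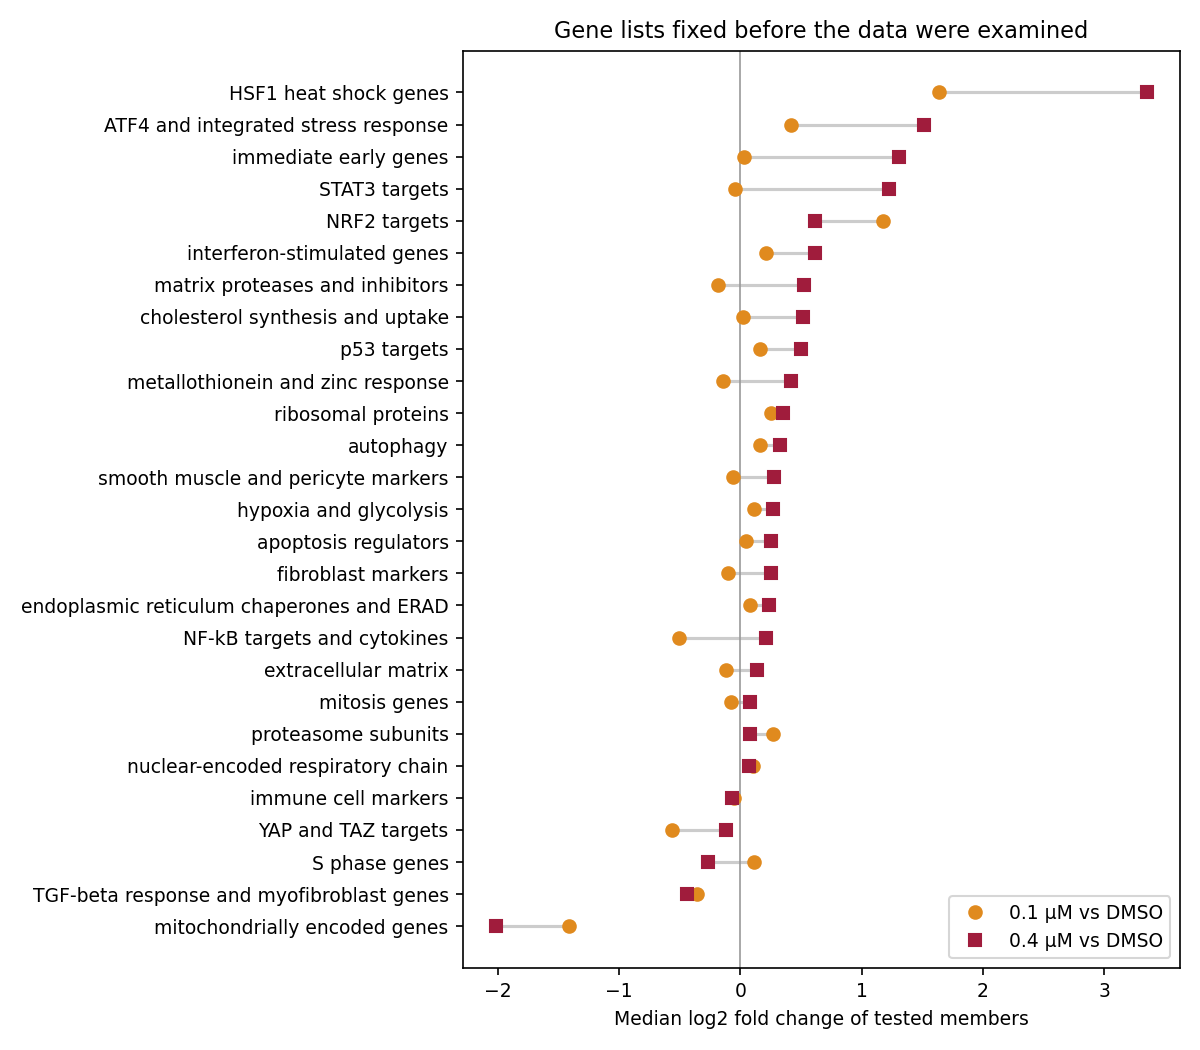
Median log2 fold change against DMSO of the 27 gene lists with a set test, at 0.1 µM and at 0.4 µM. Heat shock genes had the highest medians (1.64 and 3.36), NRF2 targets the next highest at 0.1 µM (1.18) but 0.62 at 0.4 µM, and mitochondrially encoded genes the lowest (-1.41 and -2.02). Some small medians at 0.4 µM, such as that of ribosomal proteins (0.35), changed sign with the scaling, while others, such as that of YAP and TAZ targets (-0.12), did not.

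Set beside each other, the doses shared 1098 genes higher and 1198 lower than DMSO at both, 2296 in all. Lists of these sizes drawn independently would share 978. Counts simulated for all libraries from the DMSO means, with no gene changed, shared 0.05 on average. With no gene changed the adjusted threshold calls few genes, so that count is no baseline for the 2296. Of the 1098 higher at both doses, 701 were also higher at 0.4 than at 0.1 µM and 51 lower. Across genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson's r of 0.64 against a simulated 0.50, and a covariance of 0.404 against 0.0310. The simulated values already hold the spread between libraries that the shared controls bring, so the excess lies beyond that spread. A difference common to all 3 DMSO libraries was not simulated. These libraries cannot be split into parts of at least 2, so part of the excess may still come from such a difference.

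Markers of the fibroblasts and of other cell types were followed in the same libraries. Of 14 fibroblast markers 4 were lower at 0.1 µM and 8 higher and 2 lower at 0.4 µM, where VIM (vimentin) rose by 0.59 ± 0.08 and PRRX1 fell by 0.86 ± 0.14, and their median of 0.25 became -0.04 with total-count scaling. Between doses 10 of the 14 were higher (adjusted p = 0.0487, lost with most alternatives, and adjusted p = 0.320 with an estimated correlation), and neither comparison with DMSO passed (adjusted p = 0.164 and 0.581). None of 5 immune cell markers passed in any comparison (adjusted p = 0.975, 0.987 and 0.942), with CD74 at 22.3 ± 4.43 CPM in DMSO and 20.4 ± 13.1 CPM at 0.4 µM. Without 0.4 µM replicate 1 CD74 was called lower at 0.4 µM than in DMSO (-0.80, against -0.13 with all libraries) and than at 0.1 µM (-1.21), the latter also with limma on FPKM. Smooth muscle and pericyte markers had 2 of 5 higher and 1 lower at 0.1 µM, 2 and 2 at 0.4 µM, and 1 and 2 between doses, with MCAM at 2.41 ± 0.17 and KCNJ8 at -1.31 ± 0.26 at 0.4 µM (adjusted p = 0.806, 0.906 and 0.945). The median of that list turned from 0.28 to -0.01 with total-count scaling at 0.4 µM.

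Lists with fewer than 5 tested members had no set test. Of 4 keratinocyte markers KRT16 rose at both doses (2.24 ± 0.28 and 5.17 ± 0.30, from 1.18 ± 0.45 to 42.3 ± 8.53 CPM at 0.4 µM), PERP rose and SFN fell at 0.4 µM, and the call of SFN (-2.19 ± 0.76) ended with limma on FPKM, with the replicate number as a block, and without DMSO replicate 1 (-0.67), 0.4 µM replicate 1 (-1.94) or 0.4 µM replicate 2 (-2.16). Of the 2 endothelial markers TEK, an angiopoietin receptor, fell at both doses (-2.32 ± 0.19 and -3.05 ± 0.20), and EGFL7 rose at 0.4 µM (0.83 ± 0.25), without a call under total-count scaling (0.54), with limma on FPKM, or without DMSO replicate 1 (0.68) or 0.4 µM replicate 3 (0.58). MITF, 1 of 3 melanocyte and Schwann cell markers, rose by 2.92 ± 0.26 at 0.4 µM. All 3 adipocyte markers rose at 0.4 µM, FABP4 by 1.60 ± 0.28, LEP by 1.96 ± 0.29 and CIDEC by 0.63 ± 0.10, and FABP4 also rose at 0.1 µM (2.79 ± 0.29). Of 2 aryl hydrocarbon receptor targets, CYP1B1 fell at both doses (-0.55 ± 0.09 and -0.85 ± 0.09) and TIPARP rose at 0.4 µM (1.49 ± 0.11).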

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

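Of the tests here, those of scaling, even loss and new transcript for mitochondrial genes, of scaling and general return for NRF2 targets, of depth for lncRNA genes, and the genes listed as moving oppositely at the 2 doses were chosen only after the result was seen.

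Some genes moved to opposite sides of DMSO at the doses: 72 were higher at 0.1 µM and lower at 0.4 µM, and 105 were lower at 0.1 µM and higher at 0.4 µM. By edgeR's quasi-likelihood calls against DMSO, 443 and 537 would be expected if the doses were independent, which they are not, as both are compared with the same DMSO libraries. Among the first kind the log2 difference of 0.4 from 0.1 µM was -2.70 for UBE3D, -2.64 for TNFSF18, -2.19 for UFSP1 and -2.06 for HLX. Among the other kind it was 3.05 for ZBTB16, 3.04 for KLF4, 2.91 for SOCS3 and 2.39 for THBD. These 8 genes were chosen after their values were seen, SOCS3 being named by the rule as well. The opposite calls were made with TMM scaling only, and for genes near DMSO at 0.4 µM the side depends on the scaling. THBD lay at 0.42 ± 0.08 against DMSO at 0.4 µM, where the median of all genes was 0.03 with TMM and -0.26 with total-count scaling. A signal also appeared in the 23068 genes below the expression filter, which the comparisons do not use: 166 were higher and 103 lower at 0.1 µM, and 1563 were higher and 443 lower at 0.4 µM.

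Mitochondrially encoded transcripts were lower at both doses. The choice among the scalings tried did not account for this, since the highest median of the 13 mRNAs at 0.4 µM over them was -2.02. An even loss of all mitochondrial RNA is argued against by the rRNA genes: the lower of the pair lay at 0.38 at 0.1 µM, above 0, and at -1.25 at 0.4 µM, nearer to 0 than the least negative mRNA at -1.74. The tRNA genes, which such libraries register mainly as unprocessed precursor, had a median of -3.79 at 0.4 µM, lower than the mRNAs, and 21 of 22 were called lower. Less new mitochondrial transcript may therefore be part of the pattern, while a change in polyadenylation, on which capture depends, was not tested and stays open.

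Of the 35 NRF2 targets 20 were lower, 6 higher and 9 not called at 0.4 µM against 0.1 µM, and the camera call of the list (adjusted p = 0.000338) was lost with an estimated correlation (adjusted p = 0.348). Medians over the scalings tried ran from -0.72 to -0.43, the latter with TMM, so the choice among them did not account for it. All of these scalings are relative, so they cannot show a shift common to all genes. A general return of genes raised at 0.1 µM would lower other genes as often, but 19.0% of the 1358 other genes higher at 0.1 µM were lower at 0.4 µM against 60% (18 of 30) of the NRF2 targets (Fisher's exact test, two-sided p = 1.22e-06, where genes are not independent replicates). The other genes were not matched on the size of their rise at 0.1 µM. A return of strongly raised genes in general is therefore not excluded. Of 10000 random lists matched on genomic span and expression 0 had a median as low, which puts the list at percentile 0 and argues against length and expression level. A weaker response of part of these targets at the higher dose may be biological, as a hypothesis found on these data, and the timing of the response, with a single time point, was not tested.

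With the filterByExpr filter, transcripts annotated as lncRNA were shifted upward at 0.4 µM, with a median of 0.65 over 3110 genes. Of these 725 were higher and 206 lower, against a median of 0.02 for 14780 coding genes. At 0.1 µM the lncRNA median was 0.27, with 169 genes higher and 52 lower, against a coding median of -0.02. The lncRNA share of all counts was 1.05 ± 0.16% in DMSO, 1.61 ± 0.55% at 0.1 µM and 1.55 ± 0.19% at 0.4 µM. LncRNA and coding genes were not matched on expression level, so an effect of low expression was not tested. Depth did not account for the shift at 0.4 µM. After thinning to equal totals the lowest 0.4 µM library had 2497 lncRNA genes with 12 or more counts, above the highest DMSO library at 2022. For transcription running past the ends of upstream genes, lncRNA genes near and far from gene ends were compared. The median of the 397 within 10 kb past a gene end minus that of the 2230 with none within 50 kb was -0.10 (two-sided permutation p = 0.228). No excess near gene ends was seen. The 2230 may include lncRNA genes that overlap a coding gene on the same strand. Whether the upstream gene itself rose was not used, so this explanation was not excluded. Genomic DNA could not be excluded: the log2 ratio of the summed counts of 141 olfactory receptor genes was -0.14 with an SE of 0.37, and although that ratio plus 2 SE (0.61) lay below the lncRNA median, as had been set beforehand as the bound, 2 SE is too narrow for 3 libraries against 3, and the upper 95% bound on 4 degrees of freedom was 0.89. That bound, chosen after the values were seen, lies above the lncRNA median, so this explanation may still hold.

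The F-test over 3 groups was repeated on other groupings of the 9 libraries. Of 100 splits, drawn at random with the real one included, 1 gave as many genes, the real one with 7900, and the highest other gave 5528. The labels do not say that the libraries of a group came from separate cultures. Splits of libraries therefore cannot exclude chance differences between cultures. For each pair of groups 6 libraries make 10 splits, too few for a share under 0.05. In fits of the pair alone the real split called 3219 genes for 0.1 µM against DMSO, 7136 for 0.4 µM against DMSO and 6230 between doses, and the highest other split called 1, 0 and 0.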

How the results depend on the processing

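The alternatives DESeq2, filterByExpr, median-of-ratios factors on counts, total-count scaling, counts divided by 4 and leaving out mitochondrially encoded genes were chosen after seeing the data. Limma on log2(FPKM + 0.5) was the test first named in the design. At 0.4 µM it called 2272 genes higher and 5161 lower than DMSO, against 3753 and 3637 with the reported test. Over all alternatives, single genes kept direction and side of the threshold in 12352 comparisons with the reported value, gained a call in 138, lost it in 253 and reversed in 13. Lists did so in 1898, 18, 96 and 1, and of the counts 265 stayed within 1.5 times and 33 did not. Sign changes of values called neither way were counted as kept, 144 for 41 gene results and 112 for 29 list results. With FPKM as deposited or with total-count scaling, fewer genes were higher at 0.4 µM than DMSO: 2272, 2265 and 2277 with limma on FPKM plus 0.5, 0.1 and 1, and 2255 with total counts. FPKM is itself scaled to library depth, so these settings are not separate checks. The median of all genes was -0.22 with FPKM plus 0.5 and -0.26 with total counts. Between doses these gave 1897, 1870, 1897 and 1799 higher and 4890, 4893, 4886 and 5048 lower, which follows the shift of all genes under those scalings. Limma on FPKM called 9 lists at 0.4 µM with each pseudocount, and 9 with quantile normalisation; the cause was not tested. The stricter filter, with 6172 genes to test, called 2178 higher and 2126 lower at 0.4 µM, 1929 and 1848 between doses and 4622 over 3 groups. A 2-fold minimum, by construction, left 366 and 238 at 0.1 µM, 1360 and 1223 at 0.4 µM, 967 and 791 between doses and 445 shared. An estimated correlation left 4, 0 and 0 lists. RPL4 reversed at 0.4 µM to -0.05 with limma on FPKM (-0.050927, -0.050984 and -0.050855 with 0.5, 0.1 and 1), to -0.23 with quantile normalisation and to -0.056 with total counts, and between doses to -0.03 (-0.031052, -0.031086 and -0.03101), -0.17 and -0.056. Quantile normalisation also reversed the ribosomal list at 0.4 µM (-0.033) and, between doses, MT2A (-0.19), RPL3 (-0.026) and RPS2 (-0.0038); the cause was not tested. Leaving out each library gave 953 to 1600 higher and 1067 to 1977 lower at 0.1 µM, 3269 to 3718 and 3274 to 3761 at 0.4 µM, 2873 to 3361 and 2789 to 3183 between doses, 7125 to 7919 over 3 groups, 1554 to 2486 shared, and 11 to 13, 14 to 15 and 11 to 14 lists. Lower genes at 0.1 µM moved over 1.5 times without DMSO replicate 3 (1067) and 0.1 µM replicate 2 (1083). With the replicate number as a block, 1264 were higher and 1417 lower at 0.1 µM, 3692 and 3549 at 0.4 µM, and 3194 and 3044 between doses, but the numbers did not pair the libraries: residual r between libraries of the same number ran from -0.21 to 0.19. In simulation 1.5-fold changes were mostly missed (recovery 26.9% to 40.3%), but 147 to 158 genes were called there against 3017 to 7390 in the data, so the adjusted threshold was stricter and these rates do not carry over to the data.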

Other observations

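All gene sets and genes in this part, from the Gene Ontology terms given for each gene in the deposited table, were chosen after their values were seen, and were computed with TMM scaling only. Genes of ribosome biogenesis fell at 0.4 µM: of 89 tested, 70 were lower and 6 higher than DMSO, with a median log2 change of -0.95 (camera adjusted p = 3.35e-13 over 1086 terms, and adjusted p = 0.701 with an estimated correlation). NOL11, which acts in rRNA transcription and processing, fell by 2.57 ± 0.09, WDR12, part of a complex that matures the large subunit, fell by 1.76 ± 0.07 and MTERF3, a mitochondrial transcription factor family member, fell by 2.58 ± 0.11 (SE, n = 3 libraries per group). The small-subunit processome had 31 of 35 genes lower and 0 higher by edgeR's quasi-likelihood test, with a median of -1.12 (adjusted p = 4.87e-09, and adjusted p = 0.725 with an estimated correlation). At 0.1 µM 24 of the 89 ribosome biogenesis genes were lower, with a median of -0.15 (adjusted p = 0.0478, and adjusted p = 0.998 with an estimated correlation). Between doses 70 were lower and 5 higher at 0.4 µM, with a median of -0.82 (adjusted p = 2.33e-14, and adjusted p = 0.636 with an estimated correlation). The shift of all genes by -0.26 at 0.4 µM with total-count scaling is in the direction of these falls.

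Genes of phagosome acidification, mostly subunits of the vacuolar proton pump, were higher at both doses. At 0.1 µM 10 of 16 rose and none fell, with a median of 0.46 (adjusted p = 0.000206, and adjusted p = 0.977 with an estimated correlation), and at 0.4 µM 12 rose and 2 fell, with a median of 0.94 (adjusted p = 0.000240, and adjusted p = 0.738 with an estimated correlation). ATP6V1C1 rose by 0.82 ± 0.10 and 2.62 ± 0.10 at the 2 doses, ATP6V1G1 by 0.51 ± 0.08 and 2.16 ± 0.09 and ATP6V0A1 by 1.09 ± 0.08 and 1.78 ± 0.08. Actin-binding genes were lower at 0.1 µM in 54 of 170 cases and higher in 9 (median -0.19, adjusted p = 0.000336, and adjusted p = 0.977 with an estimated correlation). Genes of stress fibers were lower in 15 of 38 cases and higher in 2 (median -0.14, adjusted p = 0.0190, and adjusted p = 0.977 with an estimated correlation), among them FERMT2 at -0.83 ± 0.08, ZYX (zyxin) at -0.79 ± 0.10 and PXN (paxillin) at -0.73 ± 0.07. Over the 3 comparisons camera called 24, 56 and 86 of the 1086 terms with 15 to 200 tested genes, and 0 in each with an estimated correlation.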
